A study of Fibroporia radiculosa TFFH 294 with 7 samples.

How the data were processed

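Poly(A)-selected RNA of the brown rot fungus Fibroporia radiculosa was sequenced from hyphae growing on wood. Brown rot fungi remove cellulose and hemicellulose from wood and leave most of the lignin behind. The wood had been pressure-treated with a copper carbonate and quaternary ammonium preservative to a retention of 5.47 kg per cubic metre, per the labels. The series holds 3 libraries from day 31 of wood exposure and 4 libraries from day 154. Per the labels, each library was made from 5 ug of total RNA and filled its own lane of a single flow cell, with single-end reads of 76 nt. No lane or date is tied to a library in the labels, so no batch could be separated from the day.

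Each library has one deposited table of whole-number read counts per locus, not normalized. Bowtie 0.12.7 and edgeR are named in the submitters' processing notes, without their role or settings. The genome build, the gene models, the treatment of reads with several matching places, and the use of strand are not given in the sources used here. A read between overlapping genes, or between near-identical copies, may therefore be counted in either way, and such loci are uncertain. All 9628 rows of a table carry a number from 1 to 9628 under the header locus_tag. These numbers were matched to the locus tags of RefSeq assembly ASM31352v1, whose FIBRA tags also end at 9628 and of which 9184 are listed as genes. The match was checked with the deposited counts: the rank correlation of locus length with total count was 0.40 with the numbers aligned, and at most 0.11 with the numbers shifted by 1, 2, 3, 5 or 50 places. Of the 444 numbers without a RefSeq gene, 440 had a count of 0 in all libraries. No coordinate of that assembly is printed, because the build behind the counts is not named.

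The gene table pairs the locus tags with no product name. The gene lists fixed before the data were examined (copper handling, oxalate, oxidative enzymes, carbohydrate-active enzymes, transport, stress and growth) select members by product name or protein signature, so they stayed empty and the list tests were not run. The loci named in the report follow a rule fixed before the data were examined. For loci without a product name it names the 2 largest rises and the 2 largest falls among loci with an adjusted p under 0.05, no overlap between the days and a mean of at least 10 CPM (counts scaled by library size) in the higher day. Loci among the 5 most abundant of either day and loci named in the closing section fall outside that limit and were chosen after their values were seen.

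Counts were tested with edgeR 4.0.16 in R 4.3.3. Loci with too few reads were removed with filterByExpr, which left 8602 loci. Libraries were scaled with TMM, dispersions were estimated robustly, and day 154 was compared with day 31 by the quasi-likelihood F test over all 7 libraries. No replicate block entered this fit. P-values were adjusted by the Benjamini-Hochberg method, and a locus was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F, which is approximate. Abundances are CPM with TMM scaling, given as mean ± SD. They are not scaled by locus length, so a ranking by abundance is one of reads and not of transcripts. Log2 CPM for principal components and correlations used a prior count of 2. Single values per library were compared with a two-sided exact permutation test over all 35 splits, whose smallest p is 0.0286. Nothing in the labels says whether the libraries of a day came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

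The test was tested on simulated data for this comparison: counts for the 8602 loci were drawn from the real means, dispersions and library sizes, with 200 loci changed in each of 5 runs. It called 50.5% of the loci changed 2-fold and 97.0% of those changed 4-fold, and 5.42% of its calls were unchanged loci. Fewer loci changed in these runs than were called in the real data, so the shares do not carry over to it. Total counts ran from 17399763 to 20755234 per library, at which 3 counts equal 0.145 to 0.172 CPM. Reads carry no molecular identifiers, so limits of this kind cover counting error only. No pair of libraries was a duplicate: between replicates the chi-square of the counts was 108 to 240 times its degrees of freedom.

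Alternatives were other normalizations, other low-count filters, DESeq2 1.42.0, the edgeR exact test, limma-voom (limma 3.58.1), a replicate block, stricter thresholds, and leaving out each library. The others, 3 in number, were added after seeing the data: removing a length trend from each library, library weights in limma-voom, and leaving out the tag numbers from 8666 upwards. Adjacency of loci used consecutive tag numbers. A new scaffold was taken to begin where the start position in the gene table fell below that of the tag before. Python 3.11.15 with scipy 1.17.1 and statsmodels 0.14.6 was used for these steps.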

Results

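The transcriptome of Fibroporia radiculosa on copper-treated wood was compared between an early and a late stage of decay. At day 31 (n = 3 libraries) the wood had lost less than 5% of its compression strength, and at day 154 (n = 4) it had lost 52%. The series title names copper tolerance and wood decay as its subject, and its design text gives a single comparison, day 31 against day 154. Libraries held 18357875 to 20755234 counted reads at day 31 and 17399763 to 19647645 at day 154. Of 9628 numbered loci, 754 had no read in any library: 314 RefSeq genes and 440 numbers without a RefSeq gene. In each library, 8780 to 8829 loci were detected. The mean number of detected loci was 8796 ± 15.5 (SD, n = 3) at day 31 and 8825 ± 5.48 (SD, n = 4) at day 154, with no overlap between the days (exact permutation test, p = 0.0286, the smallest that 35 splits allow). The 5 library measures tested this way were total counts, detected loci and the shares of the 10, 50 and 100 most abundant loci. Adjusted over these 5, the p for detected loci was 0.143 and did not pass. A single measure at the smallest possible p could not pass this adjustment, so the failure does not argue against a difference.

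The 2 days were separated along the main axis of variation. Component 1 carried 63.6% of the variance of log2 CPM, with the day 31 libraries between -49.1 and -36.3 and the day 154 libraries between 22.6 and 39.5. Spearman correlations across loci were 0.978 to 0.983 within day 31, 0.948 to 0.979 within day 154 and 0.899 to 0.941 between the days. The lowest value within a day, between replicates 1 and 4 of day 154, was thus above the highest value between the days. The median SD of log2 CPM per locus was 0.28 over the 4 libraries of day 154 and 0.22 over the 3 libraries of day 31, and this difference was not tested. Component 2, with 15.1% of the variance, mainly separated replicates 1 and 4 of day 154, at 33.7 and -28.3.

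**Figure D1:**
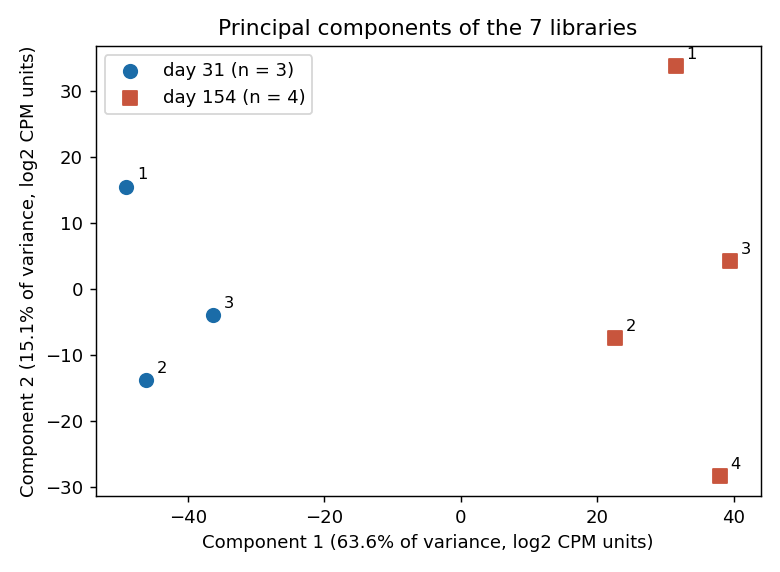
Principal components of the 7 libraries from log2 CPM of 8602 loci; the horizontal axis is component 1 (63.6% of the variance), the vertical axis component 2 (15.1%), circles are day 31, squares are day 154 and numbers are replicates. All day 31 libraries lie at -36.3 or below on component 1 and all day 154 libraries at 22.6 or above.

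Between the days, a large part of the tested transcriptome changed, in both directions. At day 154, 1136 loci were higher and 1181 were lower, 2317 of 8602 in all (26.9%; edgeR quasi-likelihood test, adjusted p under 0.05). A change of at least 2-fold was found for 1233 of them, 644 higher and 589 lower, and a change of at least 4-fold for 342, 200 higher and 142 lower. The median log2 fold change was 1.09 among the loci that rose and -0.996 among those that fell. The groups did not overlap in CPM at 3179 loci (37.0%), against 5.71% by chance in a design of 3 against 4. Scaling decided part of the balance: with library size alone 1319 loci were higher and 827 lower, with upper-quartile scaling 1394 and 971, while the median over all loci moved from 0.02 to 0.13 and 0.11 on the log2 scale.

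The direction of change went with abundance. In the quartile of tested loci with the highest mean abundance (96.8 CPM or more), 873 were called, of which 312 rose and 561 fell. In the quartile with the lowest abundance (up to 13.1 CPM), 410 were called, of which 280 rose and 130 fell. Rises thus made up 35.7% of the calls in the highest quartile and 68.3% in the lowest (Fisher's exact test, two-sided, odds ratio 3.87, 95% interval 2.99 to 5.01, p = 7.01e-28). That test was not among the planned ones. It is across called loci, which are not independent replicates, so its p and interval do not measure the spread between libraries. The corresponding shares were 47.9% and 78.4% with library size alone, and 44.8% and 76.5% with upper-quartile scaling. Each scaling moves all loci of a library by the same factor, so it could hardly change this order. A bias that depends on abundance was therefore not tested by it.

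**Figure D2:**
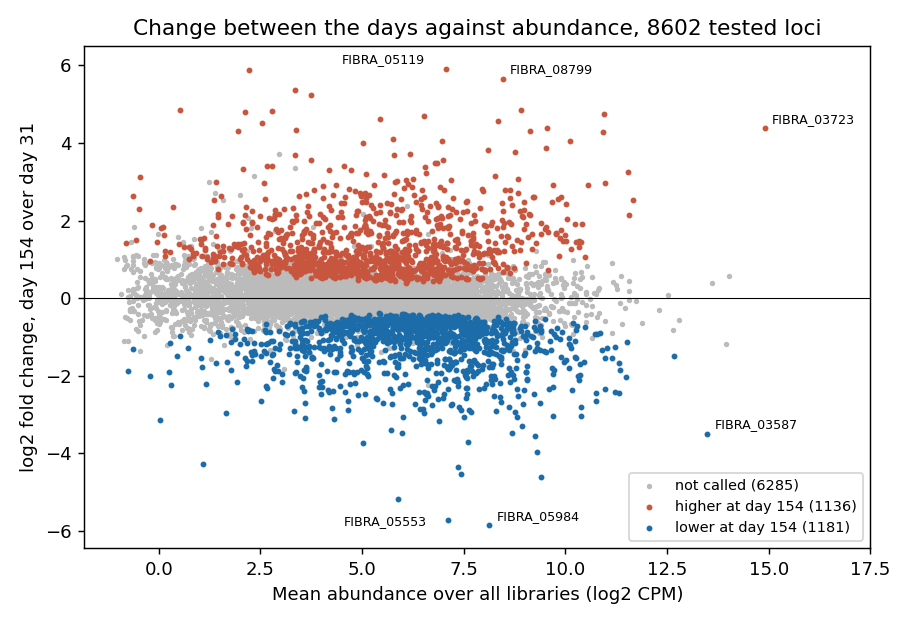
Log2 fold change of day 154 over day 31 (vertical axis) against mean abundance in log2 CPM (horizontal axis) for 8602 loci; red points are the 1136 loci called higher at day 154, blue points the 1181 called lower, grey points were not called. FIBRA_03723 stands apart at the right, with a log2 fold change of 4.38.

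A single locus led the read counts of the late stage. FIBRA_03723 took 0.242% ± 0.131 (SD, n = 3) of all counted reads at day 31 and 5.32% ± 1.35 (SD, n = 4) at day 154, where it was the most abundant locus in each of the 4 libraries. Its abundance rose from 2491 ± 1235 CPM to 51948 ± 15455 CPM, a log2 fold change of 4.38 ± 0.50 (SE; edgeR adjusted p = 0.000351). FIBRA_03587 went the other way. It had the highest mean abundance at day 31, at 23941 ± 8733 CPM (SD, n = 3), but led in replicate 1 alone, while FIBRA_05149 led in replicates 2 and 3. It fell to 2117 ± 1681 CPM at day 154 (SD, n = 4), a log2 fold change of -3.50 ± 0.61 (SE; edgeR adjusted p = 0.00313). Over the fits without single libraries this ranged from -4.17 without replicate 2 of day 154 to -3.20 without replicate 3 of day 154. FIBRA_00068, at rank 5 in abundance at day 31, fell from 10311 ± 5371 to 3654 ± 1138 CPM, with a log2 fold change of -1.50 ± 0.38 (SE; edgeR adjusted p = 0.0184). This call ended without replicate 2 of day 31 (-0.98, edgeR adjusted p = 0.0753). What these loci encode is not stated in the sources used here.

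The other 4 loci among the 5 most abundant at either day did not pass the test. FIBRA_05148 and FIBRA_05149, which carry consecutive tags, were among the 5 most abundant loci at both days. FIBRA_05149 had 23379 ± 10409 CPM at day 31 (SD, n = 3) and 10349 ± 3975 CPM at day 154 (SD, n = 4), a log2 fold change of -1.18 ± 0.41 (SE; edgeR adjusted p = 0.059). It did pass with DESeq2 (adjusted p = 0.00499) and with the edgeR exact test (adjusted p = 0.0107), and without replicate 3 of day 154 (adjusted p = 0.0347). In every other setting it did not pass. Replicate 2 of day 31 held 35395 CPM of this locus, against 17613 and 17130 CPM in replicates 1 and 3. Without that library the log2 fold change of FIBRA_05149 was -0.75 (edgeR adjusted p = 0.231). FIBRA_05148 had 12972 ± 5951 CPM and 19375 ± 8550 CPM, a log2 fold change of 0.58 ± 0.46 (SE; edgeR adjusted p = 0.378). Replicate 2 of day 31 was high for FIBRA_05148 too, at 19836 CPM against 9800 and 9278 CPM in replicates 1 and 3. Without that library its log2 fold change was 1.02 (edgeR adjusted p = 0.185). FIBRA_00199 had 10647 ± 2185 CPM and 13850 ± 8258 CPM, with a log2 fold change of 0.38 ± 0.52 (SE; edgeR adjusted p = 0.626). FIBRA_00545 had 5690 ± 966 CPM and 6005 ± 3182 CPM, with a log2 fold change of 0.08 ± 0.44 (SE; edgeR adjusted p = 0.918). The share of reads taken by the 10 most abundant loci of each library was 11.1% ± 2.46 (SD, n = 3) at day 31 and 13.1% ± 2.58 (SD, n = 4) at day 154 (exact permutation test, p = 0.4, adjusted 0.81). For the 100 most abundant loci it was 30.3% ± 1.69 and 30.4% ± 3.08 (exact permutation test, p = 0.943, adjusted 0.943).

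The largest rises were at FIBRA_05119 and FIBRA_08799. FIBRA_05119 rose from 3.86 ± 1.89 CPM (SD, n = 3) to 232 ± 194 CPM (SD, n = 4), a log2 fold change of 5.91 ± 0.95 (SE; edgeR adjusted p = 0.00238). FIBRA_08799 rose from 12.03 ± 5.37 to 606 ± 542 CPM, a log2 fold change of 5.65 ± 0.95 (SE; edgeR adjusted p = 0.00293), or 5.03 without replicate 4 of day 154. Both varied widely among the day 154 libraries, from 32.8 CPM in replicate 2 to 451 CPM in replicate 4 for FIBRA_05119 and from 114 to 1250 CPM in the same libraries for FIBRA_08799. Each of these values was above the highest value of day 31. FIBRA_08799 lies among the tags from 8666 upwards, where 34.4% of the listed loci had no read in any library.

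The largest falls were at FIBRA_05984 and FIBRA_05553. FIBRA_05984 fell from 635 ± 173 CPM (SD, n = 3) to 10.9 ± 4.796 CPM (SD, n = 4), a log2 fold change of -5.86 ± 0.40 (SE; edgeR adjusted p = 9.82e-05). FIBRA_05553 fell from 316 ± 296 to 5.99 ± 2.91 CPM, a log2 fold change of -5.72 ± 0.64 (SE; edgeR adjusted p = 0.000339). Replicate 2 of day 31 held 656 CPM of FIBRA_05553, against 119 and 173 CPM in replicates 1 and 3. Without that library the log2 fold change was -4.60.

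**Figure D3:**
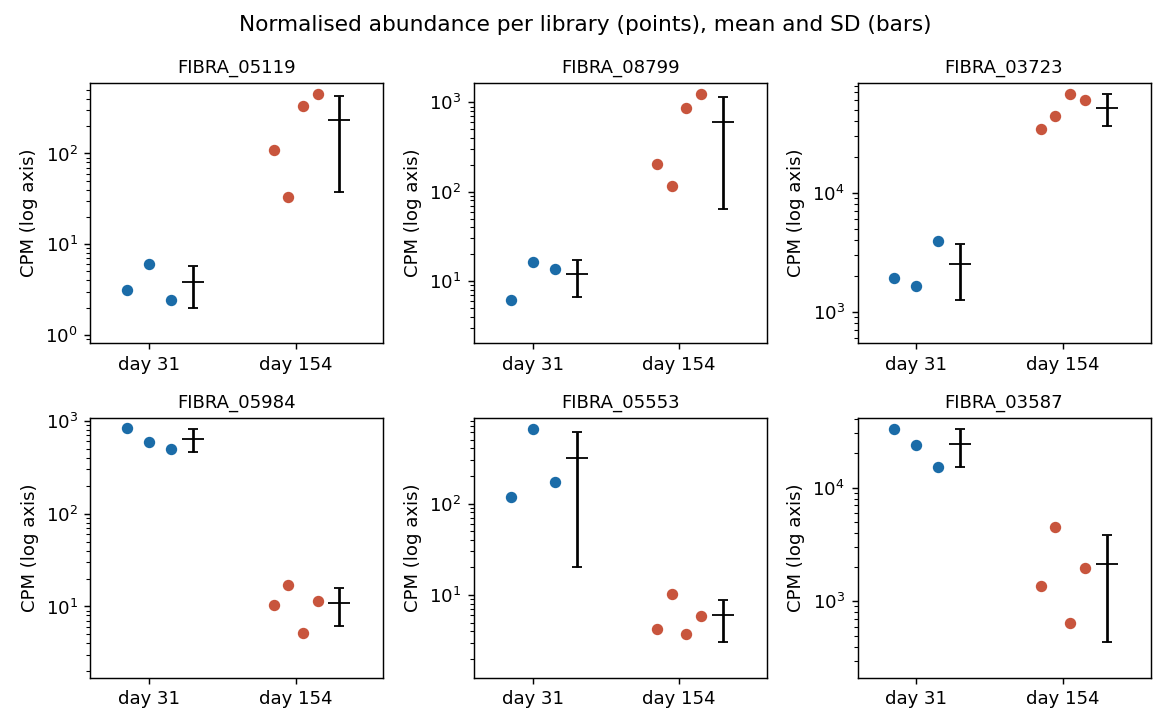
CPM per library on a log axis for the 2 largest rises, the 2 largest falls and the locus with the highest mean abundance of each day; points are libraries (3 at day 31, 4 at day 154), crosses with bars are the mean and SD. The days do not overlap at any of the 6 loci, and FIBRA_03723 reaches 34260 to 68226 CPM at day 154.

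No locus was switched on or off cleanly at this depth. At 32 loci no read was counted at day 31 but at least 1 at day 154, with at most 21 reads over the 4 libraries. At 7 loci the reverse was seen, with at most 3 reads over the 3 libraries. None of these 39 loci had 10 or more reads in every library of the day at which it was detected.

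The loci that rose took 6.06% ± 0.768 (SD, n = 3) of the reads at day 31 and 24.4% ± 1.31 (SD, n = 4) at day 154. The loci that fell took 35.2% ± 1.25 and 14.4% ± 1.98. These loci were chosen on the same libraries, so the shares give the size of the shift and are no separate test of it. FIBRA_03723 alone made up 5.08 of the 18.3 percentage points gained by the loci that rose.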

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

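The number of calls depended less on the method than on the threshold and on single libraries. Scaling moved which loci were called: with library size alone 2146 were called, 1954 of them among the original calls. With upper-quartile scaling 2365 were called, 2107 of them shared. The highest count, 2899, came with library weights in limma-voom. An edgeR test against a 1.5-fold change called 912 loci, against 1233 called with at least a 2-fold change. The count of 2317 called loci became 1176 at an adjusted p under 0.01. It was 2759 with DESeq2 (2313 of the original calls among them), 2257 with limma-voom, 2533 with the edgeR exact test, 2302 without a low-count filter and 2335 with a length trend removed. Leaving out single libraries gave 1545 (without replicate 2 of day 31) to 2285 loci, and 1071 to 1285 loci of at least 2-fold change against 1233. Of the 208 alternative values of the 11 named loci, 198 kept their direction and side of the threshold. FIBRA_00545, not called, turned to -0.093 with limma-voom and ranged from -0.19 to 0.35 over the fits without single libraries. FIBRA_00199, not called, ranged from -0.00084 without replicate 3 of day 154 to 0.71. FIBRA_03587 became -4.21 with library weights in limma-voom. The cause was not tested. With the 500 most variable loci, component 1 carried 79.6% of the variance and the gap between the lowest correlation within and the highest between days was 0.15, against 63.6% and 0.0069. These loci were picked by their variance over all 7 libraries, the day difference included, so both shifts are largely built in. Another prior count leaves rank correlations as they are, so that choice tested nothing there. The sign of the difference for the 100 most abundant loci, 0.10 percentage points, was not stable, with -1.15 to 1.35 over the fits without single libraries. Deviations from the day means correlated at 0.39, 0.17 and 0.049 for replicates 1, 2 and 3. Among these replicates, every pair of different numbers had a negative value (-0.31 to -0.014). Replicate 2 of day 31 correlated about as well with replicate 4 of day 154 (0.18), which has no partner at day 31. The value for replicate 3 was low, so the numbers were not taken to pair the libraries, but a pairing was not excluded. With a replicate block 2721 loci were called, 2116 of them also called without it, and 1184 had at least a 2-fold change; among the named loci only the call of FIBRA_00068 ended (-1.42, edgeR adjusted p = 0.0607), while the log2 fold change became 4.88 for FIBRA_05119 and 4.65 for FIBRA_08799. The other settings meant for the gene lists and their shares of counts were not run, because the lists stayed empty. In simulated data with 200 changed loci, 50.5% of the 2-fold changes were called; with the many more calls of the real data the adjusted threshold is less strict, so this share is not the one that applies here. A locus that was not called is not shown to be unchanged.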

Other observations

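The tests of runs, neighbours, silent loci and length in this part, and the loci in the search for single outlying libraries, were chosen after the main results had been seen; the count of other splits was planned. Loci that changed lay side by side more often than in shuffled calls. Of consecutive tags on the same scaffold, 64 runs of at least 3 loci were called in the same direction, against 29.9 expected when calls were shuffled over 8599 loci (permutation test, p = 0.0001, the smallest that 10000 shuffles can give). Runs of at least 4 loci numbered 17, against 3.66 expected (permutation test, p = 0.0001, again the smallest possible); 9 of them rose and 8 fell. These counts rest on the number of calls, and single libraries move them. Without replicate 1, 2 or 3 of day 31 there were 29, 32 and 32 runs of at least 3 loci (9.37, 9.21 and 13.3 expected), and without replicate 3 of day 154 there were 30 (11.3 expected). Each of these 4 fits gave 10 runs of at least 4 loci, against 0.773 to 1.26 expected. Over all 19 alternative settings there were 29 to 100 runs of at least 3 loci and 10 to 26 of at least 4, and each count lay above the highest of 1000 shuffles of its own calls. The shuffles treat neighbours as independent, but fold changes of neighbours also correlated in contrasts inside day 154 (0.106 to 0.194). A similarity of neighbours unrelated to the day would thus give such runs too. The 19 settings use the same libraries and the same kind of shuffle, so they do not remove this limit.

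The longest run held 8 loci, FIBRA_05554 to FIBRA_05561, all higher at day 154 with a median log2 fold change of 3.48. FIBRA_05560 was its most abundant member, at 53.0 ± 26.0 CPM at day 31 (SD, n = 3) and 718 ± 241 CPM at day 154 (SD, n = 4). FIBRA_05553, the tag directly before this run, was the second-largest of the falls named above (log2 fold change -5.72). FIBRA_05554 was near the detection limit, at 0.114 CPM at day 31 and 1.01 CPM at day 154. All 8 loci were called in 12 of the 19 alternative settings, and at least 6 in each of the others. A run of 6 loci, FIBRA_02722 to FIBRA_02727, rose with a median of 2.33; its last member reached 5062 ± 230 CPM at day 154 (SD, n = 4) from 877 ± 190 CPM at day 31 (SD, n = 3). The run FIBRA_04726 to FIBRA_04730 fell with a median of -1.85, and FIBRA_04728 within it went from 4410 ± 1078 to 1223 ± 522 CPM. No function is assigned to these runs here.

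The first pattern to weigh is this similarity of neighbours. Fold changes of consecutive tags on a scaffold correlated at a Spearman's rho of 0.116 (95% bootstrap interval 0.0914 to 0.139; across 7709 pairs of loci, which are not independent replicates), and of tags 2 places apart at 0.043. Reads shared between touching genes do not account for it, since pairs at least 500 bases apart still gave 0.114, and neither does similar abundance, since 0.118 remained after a trend on abundance was removed. Whether the similarity is specific to the change between days stayed open: the day contrast (0.115) lay within the range of 3 contrasts inside day 154 (0.106 to 0.194, SD 0.048; -0.0794 from the highest). A day contrast no higher than at least 1 of these had been set beforehand as evidence against such a coupling, and that was met; the rule was loosened after the value was seen, because the highest of only 3 related contrasts is a bar without a spread, and the day contrast was -0.0248 from their mean. Whether tag order alone would give it stayed open too, because the excess over pairs on either side of a scaffold boundary was 0.0782 with an interval from -0.0363 to 0.189. That neighbouring loci vary together whatever the day, or that they do so with the change between days, both remain hypotheses that may hold.

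The second pattern concerns loci without reads. Of 9184 RefSeq loci, 314 had no read in any of the 7 libraries, and 281 of them had tag numbers from 8666 upwards, where 34.4% of the loci were silent against 0.394% of the rest. Short gene models do not explain this, since among loci no longer than 559 bases the silent share was still 15.01 times higher in that range. Low expression at this depth does not either, since silent loci there outnumbered loci with 1 to 10 reads in total by 9.06 times. On scaffolds of 1 to 3 loci 41.6% were silent, 42.7 times the share on longer scaffolds, as duplicate or repeated sequence with uncounted reads would give. Foreign sequence or truly silent genes on such scaffolds would give the same, so these cannot be told apart without the sequence. A second sign of duplicates set beforehand was adjacent silent pairs that repeat the lengths of another adjacent pair. Of 119 such pairs 0 did so, but only 0.14 were expected by shuffling, so this could not decide. For the loci without reads a count of 0 could be a matter of counting rather than of expression.

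The third pattern is a weak length trend: longer loci had lower fold changes (rho = -0.0941 across 8599 loci), and in the longest quartile 209 called loci rose and 360 fell. Among the called loci it lay in that quartile only. From the shortest to the longest quartile, rises made up 50%, 57.1%, 52.0% and 36.7% of the calls. The trend does not make the calls, whose number with the trend removed was 1.01 times that without. Against a difference in RNA quality between the days, an overlap of the length slopes of the libraries had been set beforehand as evidence, and that was met. The slopes ran from -0.0029 to 0.079 at day 31 and from -0.058 to 0.036 at day 154 (exact permutation test over 35 splits, p = 0.2). It was still left open by a condition outside that rule, because the overlap was smaller than the spread of the slopes (gap -0.0388, pooled SD 0.043). A link through abundance stayed open too, since the partial rank correlation was -0.0367 once abundance was accounted for. A biological difference between long and short genes may remain as well and was not tested.

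The real assignment of libraries to days gave far more calls than any other, but this does not exclude chance assignment. The smallest p that 35 splits allow is 0.0286. Every other split mixes the days, which widens the spread within a group and made few calls likely in advance. Of the 35 splits of the 7 libraries into 3 and 4, only the real one (1 of 35) gave 2317 loci, and the highest other gave 23, from replicates 1, 3 and 4 of day 154 against the rest. For changes of at least 2-fold, again 1 of 35 splits gave 1233 loci, and the highest other gave 23. In the 4 libraries of day 154, 0 of 21 measures had a gap to the nearest library above Dixon's critical value, a test with little power at that number, and leaving out replicate 3 of day 154 still lowered the calls to 1651. Among the 444 tag numbers without a RefSeq gene, 4 had reads, and FIBRA_08404 had 33385 over the 7 libraries (log2 fold change 0.46, edgeR adjusted p = 0.653).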
